A study of Mus musculus with 12 samples.

How the data were processed

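The libraries were made, per the labels, by lysing sorted cells in Triton X-100, reverse transcription, amplification of the cDNA and tagmentation with Nextera XT, and were sequenced as RNA-seq. Per the submitters' processing notes, reads were handled with TopHat 1.0.0, Cufflinks, STAR 1.1.0, DESeq and DESeq2 1.1.0 against the mouse genome, build mm10 (GRCm38); the notes do not give the role of each tool, and the version numbers are as written there. The share of reads mapped and the depth of each library are not given in the sources used here.

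The deposited data held, for each of 4 comparisons, a table of rlog values per library on a log2 scale, as the file headers give it. The authors' DESeq2 results table gave the mean normalized count over the libraries of that comparison, the signal of a gene after their size factor normalization, a Wald statistic as the score of each gene, a log2 fold change, a p-value and an adjusted p. The authors' Cuffdiff table gave 1 FPKM value per group, with a p-value and a q-value. The rlog transform shrinks the values of genes with low counts towards their mean, so fold changes of such genes are understated. Folds of rlog values can be smaller than those of the authors' FPKM for well expressed genes too. In islets, the FPKM of Lag3 was 653 in 4-8 and 68.9 in 12-4.4m1, a wider difference than that of its rlog values. Nothing was imputed, and 0 columns were left out. The authors' own tests were copied as counts and directions: at 0.05 their DESeq2 tables called 21 genes higher and 8 lower between the TCRs in islets, 14 and 7 in spleen, 424 and 183 between islets and spleen for 4-8, and 290 and 108 for 12-4.4m1. Their Cuffdiff tables called 40 and 17, 42 and 42, 732 and 428, and 619 and 319.

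Columns were assigned to groups by the sample titles, which name the tissue, the TCR and a number. In the islet TCR table, 1 column of the 4-8 group carries a number that matches no title. It was used as islet 4-8, and it is called replicate 3 by elimination. Its deviations from the group mean correlated across 8168 genes, which are not independent replicates, with those of islet 4-8 replicate 3 in the tissue table (r = 0.992), against -0.332 and -0.697 for the other two. The descriptions of spleen replicate 2 of each TCR list the tissue table of the other TCR, while the columns of the tables follow the titles, which were used. The planned check of the labels by variable segments of the TCR genes could not be run, since the tables hold no symbols of such segments. Rows of 2 symbols that occur more than once, 4 in all, were left out.

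Each comparison was fitted in its own table, since each table was normalized separately. The model was limma 3.58.1 (lmFit, then eBayes with a mean-variance trend and without robust estimation) in R 4.3.3 on the rlog values of 3 against 3 libraries, with 2-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was tested if its mean normalized count in the authors' table of the same comparison was at least 10. Genes passed at an adjusted p of 0.05. All TCR differences are 4-8 minus 12-4.4m1, and all tissue differences are islets minus spleen, in log2 units with the SE of the fit; group means are given with the SD of 3 libraries. No replicate block was used, since the labels do not say that a number marks 1 mouse. A difference between 2 fold changes from separate tables was not tested. An exact permutation test of 3 against 3 cannot go below 0.1, so none is reported. Of 4 comparisons and 2 overlaps computed, all are reported.

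Gene lists, 32 in all, covered states and functions of Tregs and other T cells, metabolism and stress, and markers of other cell types that a sort could hold. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry asks whether the genes of a list move on balance in 1 direction. Counts of members are over all genes tested unless given as adjusted over the list alone. Positions and gene types are from GENCODE vM21 on GRCm38.

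The genes named were chosen by a rule. In each comparison these were the 10 largest differences in each direction among genes past the threshold whose groups did not overlap, filled by unadjusted p where fewer passed and then said not to pass. To these were added up to 4 members of each list with the smallest p, and always Foxp3, Il2ra, Ctla4, Il10, Tigit, Tnfrsf18, Areg, Ebi3, Nr4a1, Ins1 and Ins2 where measured. Predicted genes and receptor segments were left out of the largest differences. Ins1 and Ins2 were below the filter in all 4 tables, and Il10 was below it in the spleen table. The groups, the tests, the gene lists, this rule and most of the other settings tried were fixed before the data were examined.

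In simulations with the residual spread of each comparison, as moderated by eBayes, 20 data sets each had 200 planted genes. The differences were planted in the rlog values, after their shrinkage. The rates below therefore do not apply to differences in expression of the same size, which rlog shrinks first at low counts. A log2 difference of 1 was called in 95.9%, 100%, 96.6% and 97.7% of planted genes in the islet, spleen, 4-8 and 12-4.4m1 comparisons, and one of 2 in 100% in each. Of the genes called, 5.32%, 5.93%, 5.57% and 5.87% had not been planted. The list of Treg identity genes, shifted by 0.5, was called by camera in 20 of 20 data sets of each comparison. Genes were simulated as independent, while the estimated correlation within this list was 0.210, 0.201, 0.151 and 0.291 in the data. The simulation therefore cannot show how camera at the preset correlation performs for lists of correlated genes. Other software was statmod 1.5.0, jsonlite 2.0.0, python 3.11.15 and matplotlib 3.10.9.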

Results

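RNA sequencing measured the transcripts of regulatory T cells (Tregs), the Foxp3-expressing T cells that restrain immune responses, from mice of the NOD strain, which develops autoimmune diabetes. The mice were 6.8 weeks old and retrogenic, meaning that their blood cells came from bone marrow carrying introduced T cell receptor (TCR) genes. The introduced TCRs recognise insulin: 4-8 with high affinity and 12-4.4m1 with low affinity. Tregs of each TCR were sorted from the pancreatic islets, where insulin is made, and from the spleen, which gave 4 groups of 3 libraries and 12 libraries in all. The groups were compared in 4 tables of 6 libraries, each normalized on its own, so that values are comparable within a table and not between tables. Each table listed 24417 genes, of which 8212 were tested between the TCRs in islets, 9108 between the TCRs in spleen, 8981 between islets and spleen for 4-8, and 8438 between islets and spleen for 12-4.4m1. The values were log2 values, from which the total count of a library cannot be read. The mean normalized counts given by the authors summed to 898995, 1316454, 1284347 and 918913 over the genes of these tables, in that order. The median standard error (SE) of a log2 fold change was 0.193 and 0.123 in the TCR comparisons of islets and spleen, and 0.181 and 0.187 in the tissue comparisons of 4-8 and 12-4.4m1. In simulations with these spreads, a log2 difference of 0.5 planted in the rlog values was called in 20.6% of genes in islets and 77.7% in spleen. One of 1 was called in 95.9% and 100%. Differences in expression are shrunk in rlog values at low counts, so these rates overstate what is found for such genes. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries.

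The comparison of the TCRs in islets asks how Tregs with the high affinity TCR 4-8 differ from those with the low affinity TCR 12-4.4m1 in the tissue that holds their antigen. With 1 TCR of each affinity, affinity cannot be told apart from any other property of these receptors or of the mice that carried them. Islet 4-8 Tregs had more transcript of Lag3, an inhibitory receptor for MHC class II, of the chemokines Ccl3, Ccl4 and Ccl5, and of Nkg7, a granule protein of cytotoxic lymphocytes, and less of Areg, which encodes the epithelial growth factor amphiregulin. The regularized log (rlog) value of Lag3 was 9.86 ± 0.42 (SD, n = 3) in 4-8 and 7.32 ± 0.26 (SD, n = 3) in 12-4.4m1. This is a 5.84-fold difference in rlog values, as are all folds given here (log2 fold change 2.55 ± 0.21 SE, limma adjusted p = 3.16e-09). Ccl4 was 5.12-fold higher (2.36 ± 0.21 SE, adjusted p = 1.86e-08) and Nkg7 3.65-fold higher (1.87 ± 0.23 SE, adjusted p = 9.83e-06) in 4-8. Areg was 6.31 ± 0.45 in 4-8 and 7.71 ± 0.23 in 12-4.4m1 (log2 fold change -1.40 ± 0.21 SE, adjusted p = 0.000334). Foxp3, the transcription factor that defines Tregs, was 9.15 in both groups (log2 fold change -0.00 ± 0.19 SE, adjusted p = 0.996). On GRCm38 these genes are on chromosome 6 at 124904361 to 124911705 (Lag3), chromosome 11 at 83662584 to 83664683 (Ccl4), chromosome 7 at 43437073 to 43438249 (Nkg7), chromosome 5 at 91139599 to 91148432 (Areg) and chromosome X at 7573644 to 7595245 (Foxp3), all annotated as protein-coding.

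Of the genes tested in islets, 21 were higher and 9 lower in 4-8 at the adjusted p 0.05 threshold, and 557 had an unadjusted p under 0.05. The libraries of the groups did not overlap in 29 of these 30 genes, and in 11.9% of all genes tested, where chance gives 10%. The authors' own table of count tests called 22 of the 30 and gave all 30 the same sign. Other genes higher in 4-8 were Ccl3 (log2 fold change 1.73 ± 0.26 SE, adjusted p = 0.000260), Ccl5 (1.73 ± 0.26 SE, adjusted p = 0.000334), the macrophage growth factor Csf1 (1.60 ± 0.24 SE, adjusted p = 0.000260) and Srgap3 (1.53 ± 0.19 SE, adjusted p = 1.04e-05). Together with Lag3, Ccl4, Nkg7 and Areg, these passed in all 6 fits that left out 1 library. Among the Th1 genes, 14 were tested and 5 were higher: Ccl3, Ccl4, Ccl5, the cytokine Ifng (1.12 ± 0.21 SE, adjusted p = 0.00651) and the IL-12 receptor chain Il12rb2 (1.01), named after its value was seen to complete the count. Adjusted over the list alone, 6 were higher and 2 lower. The list as a whole was higher by camera (adjusted p = 9.65e-07), and not with an estimated correlation (adjusted p = 0.231). Ifng did not pass without 12-4.4m1 replicate 2 (adjusted p = 0.149). Of 10 co-inhibitory receptors, Lag3 passed, and 4 were higher and 0 lower adjusted over the list alone. Tigit, an inhibitory receptor of Tregs, was 0.75 ± 0.19 SE (adjusted p = 0.0829) and Pdcd1 0.55 (adjusted p = 0.411). The co-inhibitory list had an adjusted p = 1.5e-07 by camera and 0.0302 by fry, against an adjusted p = 0.0997 with an estimated correlation.

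Of 14 suppressive mediators tested in islets, Lag3 and the cytokine Il10 were higher in 4-8 and Areg lower, and 5 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0116, higher; adjusted p = 0.379 with an estimated correlation). Il10 was 7.64 ± 0.75 in 4-8 and 6.31 ± 0.73 in 12-4.4m1 (SD, n = 3 each), or 2.51-fold higher (1.33 ± 0.29 SE, adjusted p = 0.0301). Its groups overlapped, and it passed in 2 of the 6 fits that left out 1 library, with an adjusted p up to 0.475. Il10 also separated by the style of the library titles: it was 5.88 to 6.79 in the 3 libraries titled as Treg and 7.16 to 8.20 in the 3 titled as R, a log2 difference of -1.58. With title style in the fit its TCR difference was 0.90 ± 0.18 SE (adjusted p = 0.00428). Ebi3, a subunit of IL-35, was -0.76 ± 0.19 SE (adjusted p = 0.0862), the activation-induced receptor Nr4a1 -0.57 (adjusted p = 0.382), the inhibitory receptor Ctla4 0.18 (adjusted p = 0.905), the IL-2 receptor chain Il2ra 0.42 (adjusted p = 0.756) and Tnfrsf18, which encodes GITR, 0.28 (adjusted p = 0.844). Of 9 tissue repair genes of Tregs, Il10 was higher, and Areg and the IL-33 receptor Il1rl1 (-0.88, adjusted p = 0.0429) were lower. The list did not pass (adjusted p = 0.308), and its median was 0.08 while its mean was -0.09. Of 13 listed genes of Th2 and Th17 cells, 3 were tested, and the chemokine receptor Ccr4 was lower (-0.96, adjusted p = 0.0301). Gata3, another of the 3, did not pass, and its authors' FPKM was 94.8 in both groups (Cuffdiff q = 0.997). The list was lower (camera adjusted p = 0.00152, and adjusted p = 0.190 with an estimated correlation). Ccr4 passed in 3 of the 6 fits that left out 1 library (adjusted p up to 0.350) and Il1rl1 in 1 (adjusted p up to 0.219). None of 15 glycolysis genes passed over all genes, while 3 were higher adjusted over the list alone, and the list was higher (camera adjusted p = 0.000111; adjusted p = 0.231 with an estimated correlation). None of 15 heat shock and dissociation stress genes passed, 5 were lower adjusted over the list alone, and the list had a median of -0.39 (camera adjusted p = 1.5e-07; adjusted p = 0.231 with an estimated correlation). None of 24 early genes induced by TCR signalling passed, nor did the list (camera adjusted p = 0.0708). It pointed lower in 4-8, with a median of -0.10, and 2 were higher and 3 lower adjusted over the list alone. Of the 25 lists tested, 7 were higher and 5 lower by camera, 0 passed with an estimated correlation and 1, the co-inhibitory receptors, passed by fry. The gene count fell to 9 (8 higher, 1 lower) without 12-4.4m1 replicate 1 and to 11 (9 higher, 2 lower) without 12-4.4m1 replicate 2. The titles of 4-8 replicate 2 and 12-4.4m1 replicates 1 and 2 are in another style: with title style in the fit 52 genes passed (35 higher, 17 lower), all 30 among them, and without these libraries 16 passed (10 higher, 6 lower), of which 8 were among the 30, with 1 library left for 12-4.4m1.

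**Figure D1:**
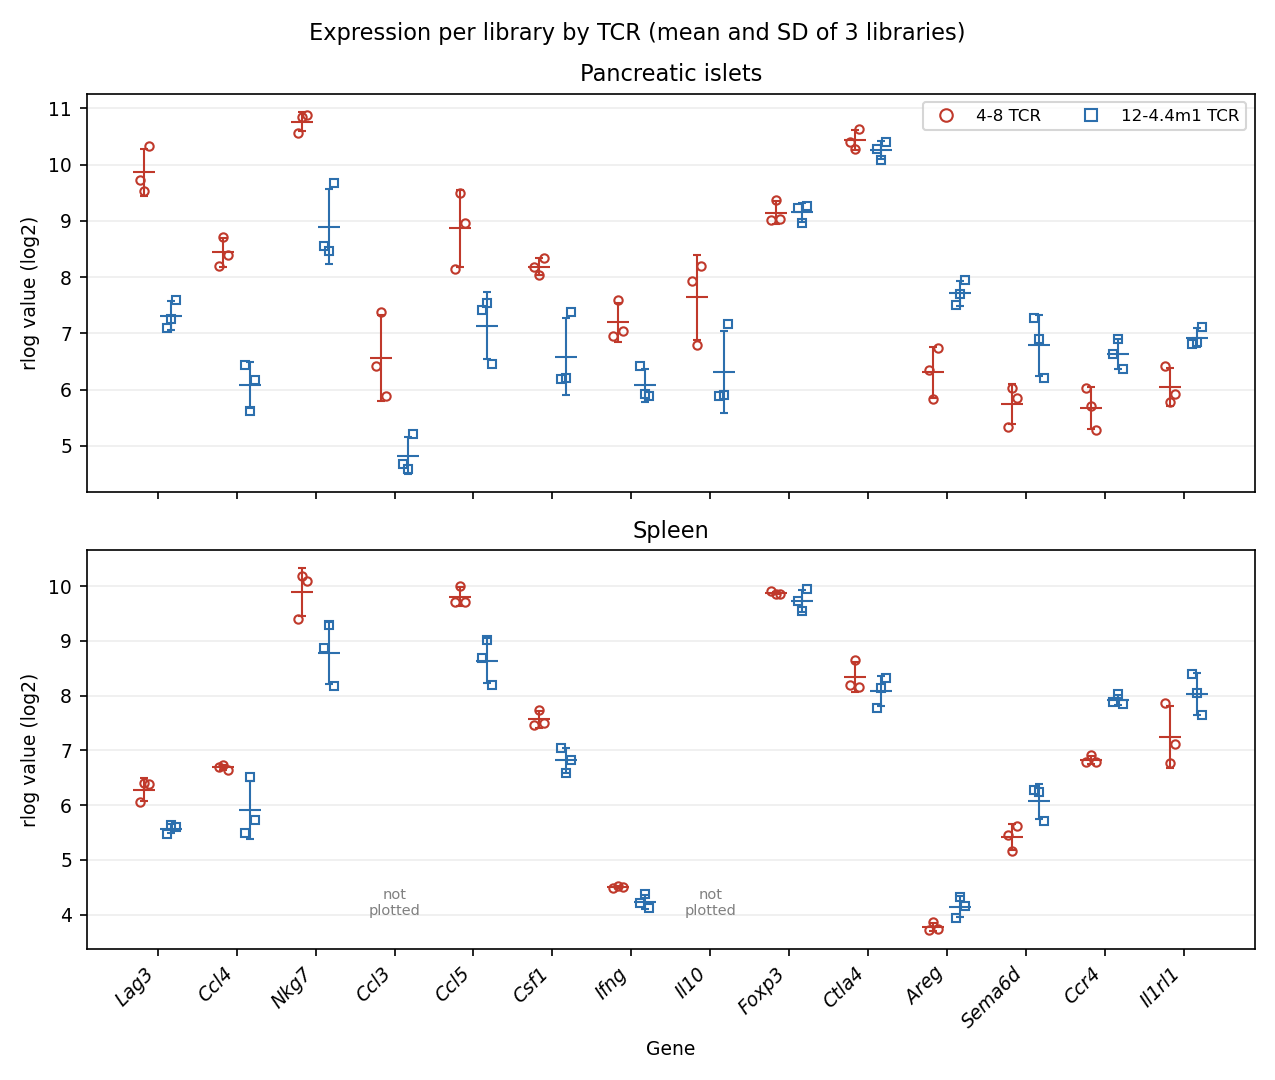
rlog values (log2, vertical axes) of 14 genes in each library of 4-8 (circles) and 12-4.4m1 (squares) Tregs, in islets (top) and spleen (bottom), with the mean and SD of 3 libraries as bars. In islets the libraries do not overlap for Lag3 (9.86 and 7.32 on average) or Areg (6.31 and 7.71), and overlap for Foxp3 (9.15 in both) and Il10; Ccl3, with an adjusted p of 0.735 in spleen, and Il10, below the expression filter there, are not plotted in spleen.

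The comparison of the TCRs in spleen asks the same question away from the islets. Spleen 4-8 Tregs had more transcript of Ccl5, of Nkg7, of the costimulatory receptor Cd27 and of the cytotoxic protease Gzmb, and less of the chemokine receptors Ccr4 and Ccr6 and of the nuclear receptor Rora. Ccl5 was 9.80 ± 0.18 in 4-8 and 8.64 ± 0.41 in 12-4.4m1 (SD, n = 3 each; log2 fold change 1.17 ± 0.15 SE, adjusted p = 6.21e-05). Cd27 was 8.82 ± 0.06 and 7.83 ± 0.22 (0.99 ± 0.13 SE, adjusted p = 6.21e-05), and Ccr4 was 6.83 ± 0.07 and 7.92 ± 0.09 (-1.09 ± 0.12 SE, adjusted p = 1.67e-05). Nkg7 (1.11 ± 0.19 SE, adjusted p = 0.00535), Gzmb (0.98 ± 0.14 SE, adjusted p = 0.000458), Rora (-1.03 ± 0.13 SE, adjusted p = 6.21e-05) and Ccr6 (-0.80 ± 0.12 SE, adjusted p = 0.00109) also passed, and these 7 genes passed in all 6 fits that left out 1 library. Of them, Ccr6 did not pass with Xist level in the fit (-0.70 ± 0.17 SE, limma adjusted p = 0.0855). Foxp3 was 0.14 (adjusted p = 0.835), Ctla4 0.26 (adjusted p = 0.721), Areg -0.37 (adjusted p = 0.155) and Ebi3 -0.42 (adjusted p = 0.357). Areg had a low mean normalized count in spleen (17.7), so its rlog fold is shrunk. The authors' FPKM of Areg there was 4.38 in 4-8 and 22.5 in 12-4.4m1 (Cuffdiff q = 0.141).

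In spleen, 19 genes were higher and 20 lower in 4-8, and 722 had an unadjusted p under 0.05. The libraries of the groups did not overlap in 38 of these 39, the exception being Xist, and in 13.3% of all genes tested, where chance gives 10%. The authors' table of count tests called 21 of the 39 and gave all 39 the same sign. Of 14 Th1 genes, Ccl4 (0.78 ± 0.17 SE, adjusted p = 0.0381), Ccl5 and Gzmb were higher and the IL-18 receptor chain Il18rap lower (-0.57, adjusted p = 0.0396), and 6 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000201; adjusted p = 0.132 with an estimated correlation). Ccl4 and Il18rap each passed in 1 of the 6 fits that left out 1 library (adjusted p up to 0.135 and 0.168). Of 13 listed genes of Th2 and Th17 cells, 3 were tested. Gata3 did not pass, with an authors' FPKM of 137 in 4-8 and 125 in 12-4.4m1 (Cuffdiff q = 0.770). The list result (camera adjusted p = 6.11e-06, fry adjusted p = 0.00149, and adjusted p = 0.132 with an estimated correlation) thus rests on Ccr4 and Ccr6, which were lower. The same 2 genes were the members of the 21 homing and adhesion genes that passed, while 1 was higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0361; fry adjusted p = 0.0261; adjusted p = 0.298 with an estimated correlation). Of 14 suppressive mediators, Gzmb and Lag3 (0.71 ± 0.13 SE, adjusted p = 0.00669) were higher, and 3 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0417; adjusted p = 0.468 with an estimated correlation). Lag3 did not pass without 4-8 replicate 3 (adjusted p = 0.0817). None of 17 genes of the TCR complex and proximal signalling passed over all genes, 3 were higher adjusted over the list alone, and the list was higher (camera adjusted p = 0.00180; fry adjusted p = 0.0261; adjusted p = 0.132 with an estimated correlation). Of 12 IL-2 and STAT5 targets, the IL-2 receptor chain Il2rb was higher (0.57, adjusted p = 0.0391; up to 0.369 with 1 library left out), as was the list (camera adjusted p = 0.00546; adjusted p = 0.298 with an estimated correlation). Lists that mark RNA quality and other cells moved as well. None of 8 heat shock and dissociation stress genes, 74 ribosomal protein genes or 4 myeloid markers passed over all genes, and adjusted over the list alone 2 heat shock genes were lower and 1 myeloid marker was higher. The heat shock list was lower in 4-8 (camera adjusted p = 0.00546; adjusted p = 0.298 with an estimated correlation), the ribosomal list higher (camera adjusted p = 0.0194; adjusted p = 0.670 with an estimated correlation) and the myeloid list higher (camera adjusted p = 0.0300; adjusted p = 0.468 with an estimated correlation). Of the 24 lists tested, 9 were higher and 6 lower by camera, 3 passed by fry and 0 with an estimated correlation (smallest adjusted p = 0.132). The gene count fell to 14 (8 higher, 6 lower) without 4-8 replicate 3, 16 (8 higher, 8 lower) without 12-4.4m1 replicate 2 and 23 (12 higher, 11 lower) without 4-8 replicate 2. The descriptions of replicate 2 of each TCR list the tissue table of the other TCR: with these libraries exchanged, limma called 0 genes, with 244 at an unadjusted p under 0.05, and with both left out 11 (7 higher, 4 lower).

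Between the TCR comparisons of islets and spleen, 8049 genes were tested in both. Ccl4, Ccl5, Csf1, Lag3, Nkg7 and the antimicrobial protein Pglyrp1 were higher in 4-8 in both tissues, 6 genes where 0.0425 would be shared if calls were independent. Ccr4, the surface receptor Fcrl1, the semaphorin Sema6d and the Rac activator Tiam1 were lower in both, 4 genes where 0.0212 would be shared. Pglyrp1, Fcrl1 and Tiam1 fall outside the rule for named genes in 1 or both tissues and were named after their values were seen, to complete these counts. No gene was called in opposite directions. With Xist level in the fit, Csf1, Pglyrp1, Fcrl1, Sema6d and Tiam1 kept their sign in spleen but did not pass there (limma adjusted p = 0.0773 to 0.416). Of the 27 genes called in islets, 26 had the same sign in spleen, and of the 38 called in spleen, 35 had the same sign in islets. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.216 and rho = 0.123. The tables were normalized separately, and whether a gene's TCR difference was larger in islets than in spleen was not tested.

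**Figure D2:**
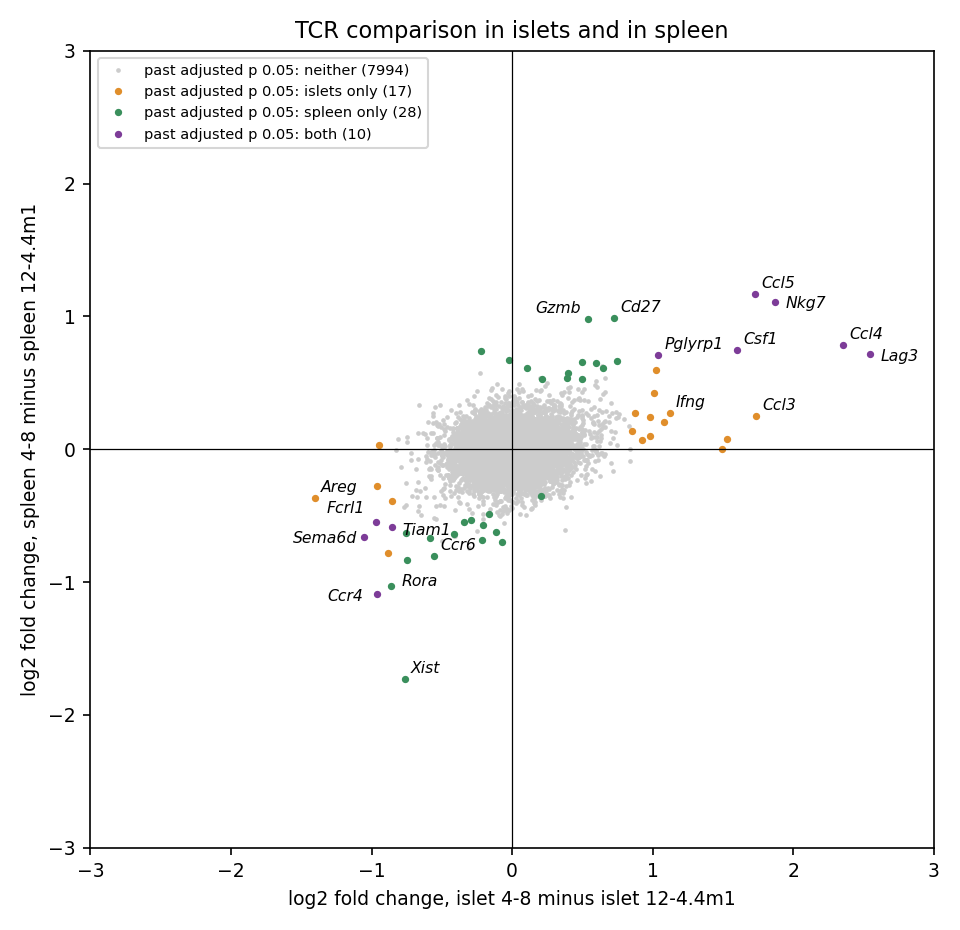
log2 fold change of 4-8 minus 12-4.4m1 in islets (horizontal axis) and spleen (vertical axis), 1 point per gene tested in both tissues, colored by where the adjusted p passed 0.05. The 10 genes past the threshold in both tissues lie in the quadrants of equal sign, with Lag3 at 2.55 in islets and 0.71 in spleen. Lag3 had a lower mean normalized count in spleen (65.2, against 653 in islets), so its rlog fold is shrunk more there.

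The comparison of islets with spleen asks what sets Tregs in the target tissue apart from those in a lymphoid organ. In 4-8, islet Tregs had far more transcript of Fos, a transcription factor subunit induced early after stimulation, and of the heat shock protein gene Hspa1a. They also had more Lag3, Il10 and Ctla4, and less of Klf3, a repressor of the Krüppel-like family, and of Il7r, the IL-7 receptor chain of resting T cells. Fos was 8.56 ± 0.11 in islets and 4.32 ± 0.29 in spleen (SD, n = 3 each; log2 fold change 4.24 ± 0.18 SE, adjusted p = 1.19e-10). Lag3 was 10.27 ± 0.41 and 7.25 ± 0.19 (3.02 ± 0.18 SE, adjusted p = 8.27e-09), Il10 7.86 ± 0.82 and 4.82 ± 0.32 (3.04 ± 0.29 SE, adjusted p = 2.41e-06), and Ctla4 10.71 ± 0.17 and 8.69 ± 0.26 (2.03 ± 0.15 SE, adjusted p = 1.52e-07). Klf3 was -2.09 ± 0.19 SE (adjusted p = 1.03e-06) and Il7r -1.48 ± 0.18 SE (adjusted p = 5.12e-05). Foxp3 was -0.06 (adjusted p = 0.854). Fos lies on chromosome 12 at 85473890 to 85477273 and Il10 on chromosome 1 at 131019845 to 131024974.

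In 4-8, 462 genes were higher and 255 lower in islets, and 1998 had an unadjusted p under 0.05. The libraries of the groups did not overlap in 707 of these 717 genes and in 27.4% of all genes tested, where chance gives 10%; the authors' table of count tests called 572 of them. Of 24 early genes induced by TCR signalling, 17 were higher, among them Nr4a1 (2.27), Nr4a2 (2.83) and Tnfaip3 (2.17), and 21 were higher and 1 lower adjusted over the list alone (camera adjusted p = 3.73e-30; adjusted p = 0.00349 with an estimated correlation). Of 13 heat shock and dissociation stress genes, which share Fos, Fosb and Jun with the early genes, 12 were higher, with Hspa1a at 4.15 ± 0.20 SE and Hspa1b at 3.94 (camera adjusted p = 6.89e-29; adjusted p = 0.00349 with an estimated correlation). Of 10 co-inhibitory receptors, 7 were higher, among them Lag3, Ctla4, Tigit (1.75) and Pdcd1 (1.24) (camera adjusted p = 5.41e-11; adjusted p = 0.0219 with an estimated correlation). Of 15 glycolysis genes, 10 were higher, among them the glucose transporter Slc2a1 (1.36) and the pyruvate kinase Pkm (0.88) (camera adjusted p = 4.42e-11; adjusted p = 0.0156 with an estimated correlation). Adjusted over the list alone, 12 heat shock genes, 7 co-inhibitory receptors and 11 glycolysis genes were higher and 0 of each were lower. Of 15 suppressive mediators, 8 were higher, Areg (1.67 ± 0.24 SE, adjusted p = 0.000237) among them, and Ebi3 was lower (-0.78, adjusted p = 0.0175; up to 0.141 with 1 library left out) (camera adjusted p = 9.07e-08; adjusted p = 0.0951 with an estimated correlation). Of 20 effector Treg genes, 9 were higher, among them the chemokine receptors Ccr8 (2.30) and Cxcr6 (1.87) and the costimulatory receptor Icos (1.18) (camera adjusted p = 7.16e-06; adjusted p = 0.0951 with an estimated correlation). Of 15 resting and central Treg genes, 5 were lower, among them Il7r, Id3 (-1.42) and the exit receptor S1pr1 (-1.07), and Ccr7 was higher (1.23; adjusted p = 0.0703 in the fit that ended its call) (camera adjusted p = 0.000282; adjusted p = 0.193 with an estimated correlation). Of 18 interferon-induced genes, Ifit3 (-0.74), Usp18 (-0.90) and Rtp4 (-0.85) were lower, with adjusted p up to 0.158, 0.100 and 0.0851 when 1 library was left out (camera adjusted p = 0.000239; adjusted p = 0.272 with an estimated correlation). Of 11 markers of pancreatic acinar cells, which make digestive enzymes, 9 were higher, with Ctrb1 at 2.16 ± 0.29 SE (adjusted p = 9.69e-05) (camera adjusted p = 4.22e-10; adjusted p = 0.193 with an estimated correlation). Of the 26 lists tested, 12 were higher and 2 lower by camera, 17 passed by fry and 4 with an estimated correlation. The gene count fell to 306 (245 higher, 61 lower), 370 (268 higher, 102 lower) and 326 (247 higher, 79 lower) without spleen 4-8 replicates 1, 2 and 3, and was 1211 (694 higher, 517 lower) without islet 4-8 replicate 2.

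In 12-4.4m1, islet Tregs also had more transcript of Fos, Hspa1a and Ctla4 than spleen Tregs, and more of Areg, and less of Il7r. Fos was 8.90 ± 0.14 in islets and 4.44 ± 0.39 in spleen (SD, n = 3 each; log2 fold change 4.46 ± 0.19 SE, adjusted p = 1.51e-14). Ctla4 was 10.05 ± 0.16 and 7.83 ± 0.30 (2.21 ± 0.16 SE, adjusted p = 2.23e-10), and Areg 7.62 ± 0.24 and 5.24 ± 0.29 (2.39 ± 0.19 SE, adjusted p = 1.52e-09). Lag3 was 6.56 ± 0.27 and 5.08 ± 0.12 (1.48 ± 0.19 SE, adjusted p = 5.93e-06), Il10 5.35 ± 0.76 and 3.79 ± 0.21 (1.57 ± 0.26 SE, adjusted p = 0.000252), and Il7r was lower (-1.87 ± 0.21 SE, adjusted p = 7.42e-07). Foxp3 was 0.08 (adjusted p = 0.812).

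In 12-4.4m1, 391 genes were higher and 184 lower in islets, and 1709 had an unadjusted p under 0.05. The libraries of the groups did not overlap in 559 of these 575 genes and in 24.1% of all genes tested, where chance gives 10%; the authors' table of count tests called 387 of them. Of 23 early genes induced by TCR signalling, 17 were higher, among them Nr4a1 (2.83), Jun (2.94) and Tnfaip3 (2.29), and 20 were higher and 0 lower adjusted over the list alone (camera adjusted p = 1.1e-35; adjusted p = 0.0320 with an estimated correlation). Of 14 heat shock and dissociation stress genes, 12 were higher, with Hspa1a at 4.32 ± 0.19 SE (camera adjusted p = 1.66e-35; adjusted p = 0.0320 with an estimated correlation). Of 9 acinar cell markers, 8 were higher, with Ctrb1 at 2.32 ± 0.21 SE (adjusted p = 3e-08) and the lipase Pnlip at 1.46 (camera adjusted p = 5.24e-15; adjusted p = 0.0320 with an estimated correlation). Adjusted over the list alone, the heat shock and acinar lists had 13 and 9 genes higher and 0 lower. Of 14 suppressive mediators, 7 were higher, Tigit (1.29) among them, and 9 were higher and 0 lower adjusted over the list alone (camera adjusted p = 2.54e-09; adjusted p = 0.133 with an estimated correlation). Of 9 co-inhibitory receptors, 4 were higher, and Pdcd1 was 0.60 (adjusted p = 0.0529) (camera adjusted p = 2.8e-07; adjusted p = 0.133 with an estimated correlation). Of 20 effector Treg genes, 6 were higher, among them Ccr8 (1.88), Cxcr6 (1.44) and Icos (1.02) (camera adjusted p = 0.000736; adjusted p = 0.216 with an estimated correlation). Of 14 glycolysis genes, 6 were higher, and 10 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.53e-05; adjusted p = 0.216 with an estimated correlation). Of 17 genes of the TCR complex and proximal signalling, 4 were higher, among them Cd4 (0.86) and the kinase Zap70 (0.67) (camera adjusted p = 6.31e-05; adjusted p = 0.0609 with an estimated correlation). Of the 24 lists tested, 14 were higher and 1 lower by camera, 9 passed by fry and 3 with an estimated correlation. The gene count fell to 288 (228 higher, 60 lower) and 313 (233 higher, 80 lower) without spleen 12-4.4m1 replicates 1 and 2. With title style in the fit, where the tissue difference rests on islet 12-4.4m1 replicate 3 as the 1 islet library titled in the style of the spleen libraries, 533 genes passed, 336 of the 575 among them.

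The tissue comparisons of 4-8 and 12-4.4m1 had 8298 tested genes in common. In both TCRs 232 genes were higher in islets, where 20 would be shared if calls were independent, and 62 were lower, where 5.63 would be shared, with no gene called in opposite directions. Of the 685 genes called in 4-8, 655 had the same sign in 12-4.4m1, and of the 569 called in 12-4.4m1, 553 had the same sign in 4-8. The genes called in both included Fos, Hspa1a, Ctla4, Lag3, Il10 and Areg on the higher side and Klf3 (-1.09 in 12-4.4m1), Il7r and the Notch regulator Dtx1 (-1.74 in 4-8 and -1.16 in 12-4.4m1) on the lower side. Across genes, the log2 fold changes correlated with r = 0.707 and rho = 0.568. Lag3 differed by 3.02 in 4-8 and 1.48 in 12-4.4m1, and Areg by 1.67 and 2.39. These differences between the TCRs were not tested across the tables, and shrinkage of rlog values, stronger at lower counts, may add to them.

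**Figure D3:**
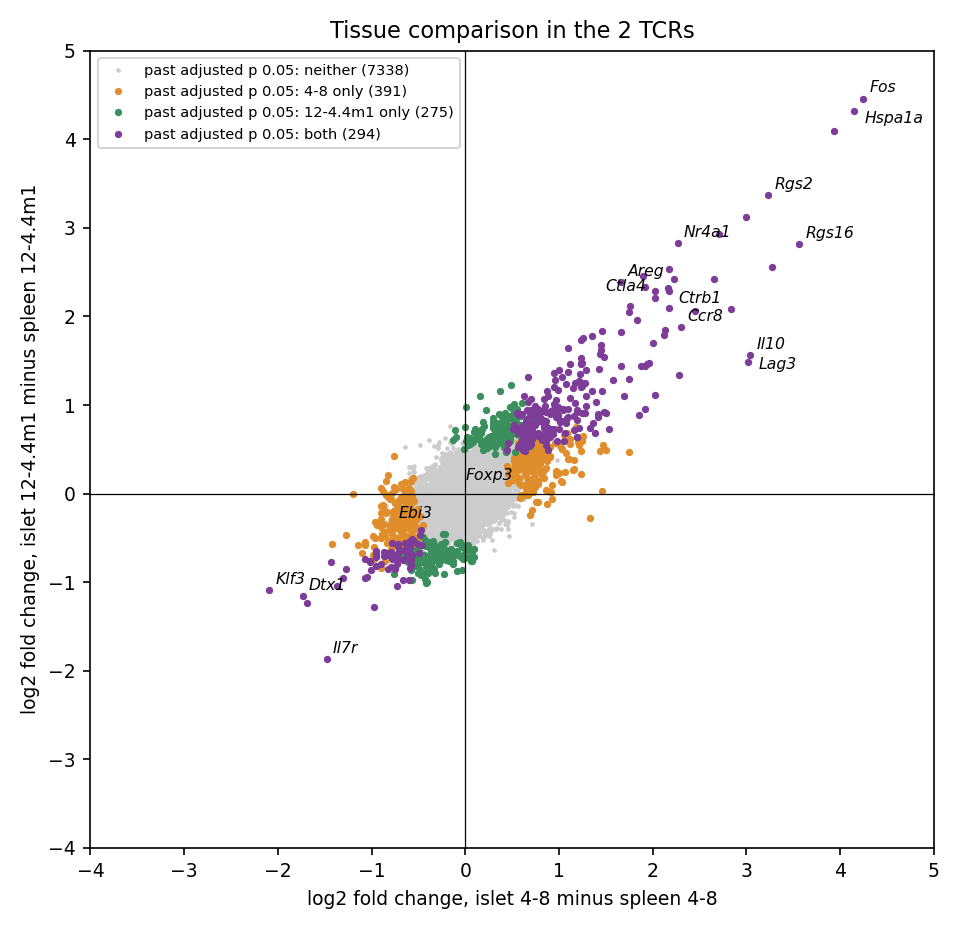
log2 fold change of islets minus spleen in 4-8 (horizontal axis) and 12-4.4m1 (vertical axis), 1 point per gene tested in both TCRs, colored by where the adjusted p passed 0.05. The 294 genes past the threshold in both TCRs lie in the quadrants of equal sign, with Fos at 4.24 and 4.46 and Il7r at -1.48 and -1.87.

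Marks of other cells and of RNA composition moved with some of these groups. In the islet table the mean normalized count was 1230 for Nkg7, 82.0 for Ctrb1, 3.56 for the insulin gene Ins2, 2.88 for Ins1, 4.66 for the macrophage gene Lyz2 and 0 for Cd8a. The 14 acinar markers tested between the TCRs in islets had a median of -0.19, and none passed (camera adjusted p = 0.00312, lower in 4-8; adjusted p = 0.450 with an estimated correlation). Of 3 NK cell markers, Nkg7 was higher in 4-8 in islets and 2 were higher adjusted over the list alone (camera adjusted p = 3.85e-05; adjusted p = 0.190 with an estimated correlation). The lectin receptor Klrd1 was 0.51 ± 0.17 SE there (adjusted p = 0.359). Between islets and spleen in 4-8, Nkg7 (1.20) and Klrd1 (0.96; adjusted p up to 0.0704 with 1 library left out) were higher in islets, the T-box factor Eomes was -0.77, and the list did not pass (adjusted p = 0.0890), with 2 members higher and 1 lower adjusted over the list alone. Xist, Rn45s, Ddx3y and Lars2 were chosen after their values were seen. The 3 islet libraries with titles in the other style (4-8 replicate 2, 12-4.4m1 replicates 1 and 2) had Xist, the transcript of the inactive X chromosome, at 9.39 to 10.5, against 6.51 to 7.5 in the other 3, and the ribosomal RNA precursor Rn45s at 14.8 to 15.1 against 13.7 to 13.9. The Y-linked gene Ddx3y was lower in them by a log2 difference of 1.05. In spleen, Xist was lower in 4-8 (-1.73 ± 0.38 SE, adjusted p = 0.0394), at 7.33, 8.39 and 9.46 in 4-8 and 8.70, 10.9 and 10.7 in 12-4.4m1, and Ddx3y was 0.49 (adjusted p = 0.429). The mitochondrial tRNA synthetase gene Lars2 was higher in islets than in spleen in 4-8 (1.44, adjusted p = 0.00900) and 12-4.4m1 (1.58, adjusted p = 2.06e-06), and Rn45s was 0.50 (adjusted p = 0.218) and 0.89 (adjusted p = 0.00159).

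**Figure D4:**
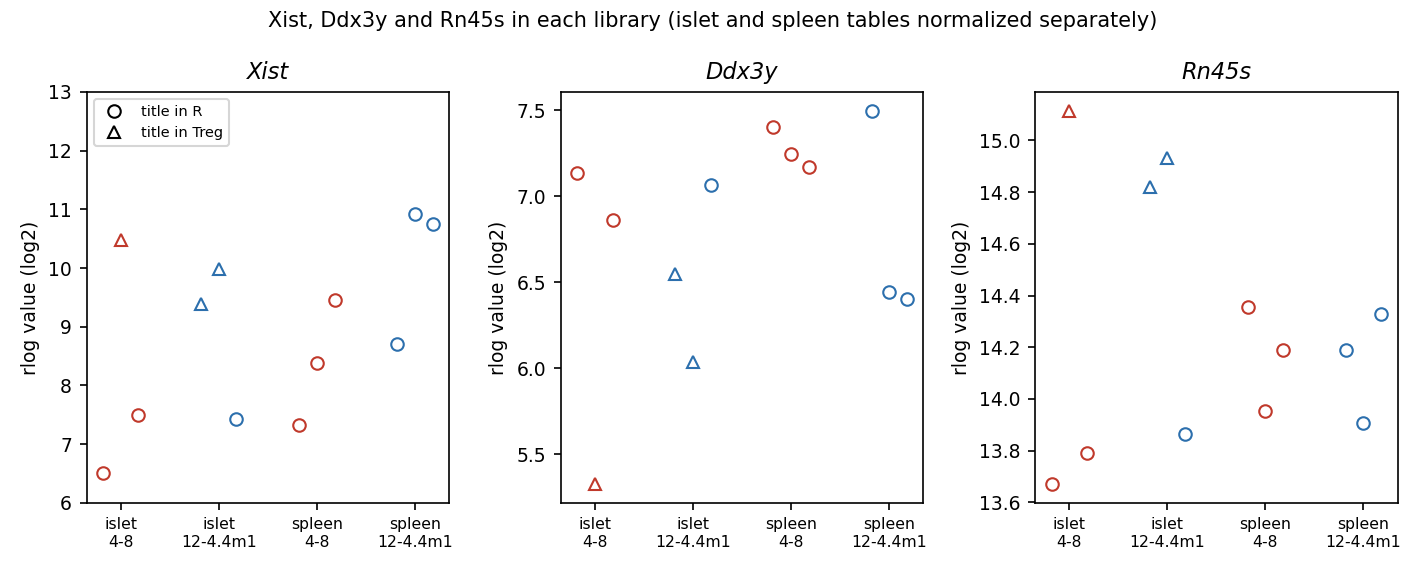
rlog values (log2, vertical axes) of Xist, Ddx3y and Rn45s in each of the 12 libraries by group; circles are libraries with a title in the style R, triangles those with a title in the style Treg. The 3 triangles, all islet libraries, have Xist at 9.39 to 10.5, above the circles in islets at 6.51 to 7.5.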

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

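The results here were found by a search of all genes called in either of a pair of comparisons, and no further test was run on them. Dscc1, a subunit of the complex that loads the replication clamp, was the 1 of 55 genes called between the TCRs in islets or spleen for which every library was separated in opposite directions in the tissues. Its log2 fold change of 4-8 minus 12-4.4m1 was 0.21 ± 0.16 SE in islets (adjusted p = 0.852, limma) and -0.35 ± 0.08 SE in spleen (adjusted p = 0.0401). It was also the 1 of 960 genes called between islets and spleen in either TCR with such a separation: islets minus spleen was 0.71 ± 0.17 SE in 4-8 (adjusted p = 0.0130) and -0.19 ± 0.17 SE in 12-4.4m1 (adjusted p = 0.578). The difference between the tissues or between the TCRs was not tested, since the tables were normalized separately. In 28 of the 55 genes and 534 of the 960 the libraries were separated in the same direction in both comparisons. Chance alone separates 3 libraries from 3 in 10% of genes, counting both directions. A search of this many genes can therefore give 1 such gene by chance. Both observations on Dscc1 rest on the same 12 libraries and are not independent of each other. No biological explanation was tested.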

How the results depend on the processing

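Settings with title style, with R titles alone and with Xist level were chosen after seeing the data; all others were planned. No gene called under any of the settings of the gene test was called in the opposite direction in the results reported above. Of the named genes over all settings, 6037 values kept their side of the threshold, 329 were weaker, 164 stronger and 3 reversed. Of the lists, 925 kept their side, 161 were weaker, 54 stronger and 1 reversed. A change of direction with neither value past the threshold was counted as kept, so these counts do not show how often direction held. Counts of genes or lists stayed within 1.5 times the main count in 126 cases and moved further in 102. Except where fewer genes or libraries were used, the cause was not tested.

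Counts below are higher, then lower. A mean normalized count of at least 100 left fewer genes: 4 lower in islets, 10 and 12 in spleen, 162 lower for 4-8 between tissues, and 257 and 117 for 12-4.4m1. Lists then numbered 4 and 3, 5 and 3, 1 lower, and 7 and 0. Quantile normalization gave 5 lower in islets and 11 lower in spleen. It also lowered the share of calls higher in islets, for 4-8 (408 and 306, 57.1% in place of 64.4%) and for 12-4.4m1 (327 and 238, 57.9% in place of 68.0%). Without the mean-variance trend, spleen had 10 and 7. Array quality weights gave 32 and 17 in islets, 30 and 32 in spleen, and 706 and 511 for 4-8 between tissues. The replicate block, for numbers that the labels do not tie to a mouse, gave 36 and 42 in spleen. It gave 37, 78, 729 and 724 genes in the 4 comparisons, with 30, 39, 654 and 574 of the unblocked calls among them. In spleen, deviations from the group means correlated at 0.120, 0.0865 and 0.0748 between libraries of the same number. For the other pairs they correlated at -0.0881 to 0.00785. In the other comparisons the 2 kinds of pair overlapped. Whether numbers mark shared mice or batches stays open.

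With both spleen libraries numbered 2 left out, spleen had 7 and 4, 4-8 between tissues 268 and 102, and 12-4.4m1 233 and 80. With them exchanged, limma called 0 and 0 in spleen (244 at an unadjusted p under 0.05), while the authors' DESeq2 and Cuffdiff tables, on libraries as titled, have 21 and 84. In that setting the log2 fold change of Csf1 was -0.0227, of Mmp9 -0.0765 and of Sema6d 0.0642. With Xist level in the fit, islets had 34 and 16 and spleen 11 and 8. With title style in the fit, islets had 35 and 17. For 4-8 between tissues it gave 695 and 517, which is no separate check, since islet 4-8 replicate 2 is the 1 library of its style there and the fit sets it aside. For 12-4.4m1 it gave 360 and 173, with 336 of the 575 calls kept and 2 lists lower, and the tissue difference then rests on 1 islet library, replicate 3, assumed to vary like the others. With R titles alone, islets had 10 higher, the lone 12-4.4m1 library being assumed to vary like the others.

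With an estimated correlation, lists numbered 0 and 0 in islets, 0 and 0 in spleen, 4 and 0 for 4-8 and 3 and 0 for 12-4.4m1. With fry they numbered 1 and 0, 1 and 2 in spleen, 14 and 3 for 4-8, and 9 and 0 for 12-4.4m1. Genes shared between the TCR comparisons were 5 at the stricter filter, 5 by the authors' count model and 16 by Cuffdiff, beside 10; between the tissue comparisons 502 by Cuffdiff, beside 294.

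Leaving out 1 library gave, in islets, 8 to 28 genes higher and 1 to 16 lower, with 4 to 11 lists higher and 3 to 5 lower. In spleen it gave 8 to 22 and 6 to 34 genes, with 3 to 11 and 2 to 6 lists. For 4-8 between tissues it gave 245 to 694 and 61 to 517 genes, with 12 to 17 and 2 to 2 lists, and for 12-4.4m1 228 to 396 and 60 to 214 genes, with 12 to 14 and 0 to 2 lists. The cell cycle list in spleen, lower at an adjusted p = 0.0113, turned to higher without spleen 12-4.4m1 replicate 2 (adjusted p = 0.639), within a range of 1.75e-05 to 0.639 as 1 library was left out. Of its 27 genes 0 passed, and with all libraries it had an adjusted p = 0.646 with an estimated correlation.

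A fit with columns of the other TCR in a table, chosen beforehand, was not run, since no table holds such a column. Depth per library is unknown, so what it limits cannot be stated beyond the filter. In islets a log2 difference of 0.5 in rlog values was called in 20.6% of simulated genes.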

Other observations

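The tests of NK cells, CD8 T cells, conventional T cells, title style and islet handling were chosen only after the results were seen. The test of male and female cells was chosen after the Xist levels were seen, with its bound set before its own result was, and the tests of other splits were chosen before.

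Of 14 Th1 genes in 4-8, 6 were higher in islets than in spleen, among them the transcription factor Tbx21 (1.24), Ifng (2.02) and Ccl4 (1.75) (camera adjusted p = 6.61e-05; adjusted p = 0.272 with an estimated correlation). Of 13 in 12-4.4m1, 3 were higher: Tbx21 (1.22), Ifng (1.11) and Cxcr6 (1.44) (camera adjusted p = 0.00382; adjusted p = 0.171 with an estimated correlation). Ccl5 was -0.63 in 12-4.4m1 (adjusted p = 0.0991). Of the Treg identity genes, Ctla4 and Lrrc32, which encodes the TGF-beta docking receptor GARP, were higher in both TCRs (Lrrc32 1.22 and 1.26). Capg passed in 4-8 (0.65; adjusted p up to 0.0930 with 1 library left out) and was 0.38 in 12-4.4m1 (adjusted p = 0.168), a difference between the TCRs that was not tested. The identity list was higher by camera in 4-8 (adjusted p = 0.00584) and 12-4.4m1 (adjusted p = 0.0416), with adjusted p = 0.272 and adjusted p = 0.423 with an estimated correlation.

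Of 15 apoptosis regulators, 4 were higher in islets in 4-8, among them the BH3-only gene Pmaip1 (1.24), and Pmaip1 was the 1 that passed in 12-4.4m1 (1.48) (camera adjusted p = 0.00503 and 0.0339; adjusted p = 0.193 and adjusted p = 0.216 with an estimated correlation). Of 9 tissue repair genes, Areg, Il10 and the transcription factor Nfil3 were higher in islets in both TCRs (Nfil3 1.96 and 1.47), and the list did not pass (adjusted p = 0.0905 and 0.0808). In 12-4.4m1 its median was -0.12 while the test pointed higher. Of 27 cell cycle genes, the replication helicase gene Mcm6 was higher in both (0.98 and 0.59, the latter with an adjusted p up to 0.204 when 1 library was left out), and the list did not pass (adjusted p = 0.0577 and 0.935). Ribosomal protein genes had 3 of 74 higher in 4-8 (adjusted p = 0.215) and 6 of 73 in 12-4.4m1 (camera adjusted p = 4.11e-05; adjusted p = 0.551 with an estimated correlation). In spleen, none of 19 interferon-induced genes passed between the TCRs, and the list was higher in 4-8 (camera adjusted p = 0.0194; adjusted p = 0.468 with an estimated correlation).

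Lag3, Ccl3, Ccl4, Ccl5, Nkg7 and Ifng were higher in islet 4-8 Tregs, and other cells in the sort may be a source of such transcripts. For NK cells, the highest mean normalized count among 6 NK receptor genes was 5.47, for Klre1. Against CD8 T cells, that of Cd8b1 was 6.57 and that of Cd8a 0. Each was under 24.6, which is 1/50 of the 1230 of Nkg7. Klrd1 (12.4), Klrk1 (3.37) and Eomes (20) of the same NK list were under it too. However, Klre1 (0.33, below the filter) and Klrd1 (0.51, adjusted p = 0.359) pointed higher in 4-8. The authors' FPKM of Klrd1 was 30.2 in islet 4-8 and 3.30 in islets with the other TCR (Cuffdiff q = 0.375). That of Eomes was 5.91 and 5.32. The counts are means over both TCRs, and no NK cells were measured to set the bound. These levels therefore cannot decide how large a share of the pattern came from NK cells. Against an uneven split of title styles, 6 of the 6 genes passed with title style in the fit, Lag3 at 2.39 ± 0.17 SE. Conventional CD4 T cells cannot be told apart from a change within Tregs by the TCR, through its affinity or otherwise, which stays open and untested. Foxp3 was -0.00497 (SE 0.185), and a small share of conventional cells would leave it so.

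Xist differed between the spleen groups, and different shares of male and female cells could underlie the other 38 genes called there. Against this, the folds with Xist level in the fit over the folds without it had a median of 0.982 (quartiles 0.852 and 1.20), and all 38 kept their sign. In that fit 13 remained past the threshold. The median SE went from 0.128 to 0.170, which lowers the number of calls. Folds of single genes changed as well, with ratios from 0.509 (Ptpn18) to 1.55 (Cd226), so smaller folds may have ended some calls too. The sex of the mice is not given in the labels, and the TCR itself stays an open explanation, untested.

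Heat shock genes, with medians of 1.89 in 4-8 and 1.91 in 12-4.4m1, were higher in islets together with early response genes. Digestion of the islets and the time to lysis may induce both, and this cannot be told apart from TCR signalling in the tissue, since every islet library was handled as islet tissue and every spleen library was not. The labels do not describe how the islets were handled. Stimulation by antigen in islets stays open as a biological explanation.

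The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, so no share under 0.1 can be had and the splits are too few for a test. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real one. The real counts were 30 in islets, 39 in spleen, 717 for 4-8 between tissues and 575 for 12-4.4m1, and the highest of the other splits gave 26, 5, 0 and 0. The 26 came from the islet split that follows title style; with title style in the fit the TCR comparison gave 52.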
